A study of Rattus norvegicus with 30 samples.

How the data were processed

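RNA was measured in 30 libraries of rat dorsal hippocampus, per the labels from snap-frozen tissue, with a column kit for fatty tissue, selection of polyadenylated RNA and the NEB Ultra II preparation. The deposited table holds raw counts per gene symbol, 1 column per library, and every column was matched to 1 sample through the column name in its description. The unit was tested on the values: all entries were whole numbers of 0 or more, and column totals differed between libraries, so the deposited counts had not been scaled. Per the submitters' processing notes, adapters were trimmed with cutadapt (version not given) and reads were aligned with STAR 2.7.0a. The counting tool, the strand setting, the genome build and the annotation are not given in the sources used here, so no coordinates are printed. Gene symbols are printed as the table writes them. A table of gene names for the rat assembly GRCr8 served to match older symbols and to order genes along chromosomes. It also named the row LOC100911498 as Xist, and the row Eif2s3 stands for Eif2s3x.

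Groups were the 8 combinations of sex, genotype and diet, with 3 or 4 libraries each. The labels also name 2 cohorts, and every group has libraries from both. In cohort 1 each female western group has only 1 library. Results of cohort 1 alone therefore rest on 1 library per genotype wherever females on the western diet enter. Counts were fitted with edgeR 4.0.16 in R 4.3.3, with 1 coefficient per group and 1 for cohort. Genes were kept by filterByExpr on the groups, with a minimum count of 10 and a minimum total of 15, which left 12547 of 17455 genes. Library sizes were adjusted by trimmed mean of M values (TMM), and each contrast used the quasi-likelihood F test, two-sided. A gene is called where its Benjamini-Hochberg adjusted p was under 0.05. The 15 planned contrasts were genotype, diet and sex as means over the other factors with equal weights, their interactions, and genotype or diet within each level of the other factors. Cohort 2 minus cohort 1 was tested as well. Unless another tool is named, every adjusted p is from edgeR for a gene and from limma 3.58.1's camera for a gene list. Log2 fold changes are given ± the standard error of the fit, computed as the size of the change over the root of F, and CPM values (counts per M, with M for mega) as mean ± SD over libraries after TMM. Where a change is given with a number of libraries, each alzheimer, western or female library was compared with a group mean. That mean was of the wildtype, chow or male libraries that shared its other 2 factors, without regard to cohort. These numbers describe the change and do not test it or show that the groups do not overlap. The p-values measure the spread between libraries, since the labels do not state in words that each library is from a separate animal.

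Groups, contrasts, tests, alternatives, the rule for named genes and 40 gene lists were fixed before the data were examined. The rule took up to 10 genes per direction for genotype, diet and sex, and up to 5 for the other contrasts, by size of the log2 fold change among called genes with an average log2 CPM of at least 1. It added called members of the lists, up to 4 examples per list that passed its test, the 3 genes with the smallest p where a contrast had no called gene, and a fixed set of marker genes. The text names part of the genes this rule gives, and some of them are not reported here. The named examples of Galnt5, Gdf3 and the diet-by-sex values of Fkbp5, Dbp and Nr1d1 were chosen after their values were seen. Of 728 list members, 685 had a row and 643 were tested. Lists with at least 4 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 37 lists of a contrast. Camera in either cohort alone and with 2 surrogate variables kept this preset, so those fits do not test it. The same lists were tested again with an estimated correlation and with fry, whose directional p asks whether a list's own genes moved in a shared direction on balance, without comparing them with other genes. The lists for blood (2 of 12 members tested), Y-linked genes (2 of 7) and the mitochondrial genome (0 of 13) were not tested. Lists overlap in some members.

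The alternatives fixed beforehand were median-of-ratios factors, no filter beyond 1 count, a filter at 1 CPM in at least 8 libraries, DESeq2 1.42.0 and limma-voom with quality weights. Others left out the cohort term, added 2 surrogate variables from sva 3.50.0, used either cohort alone or only the libraries of a stratum, and left out each library in turn. Added after seeing the data were 3 alternatives: leaving out the 3 libraries with the highest mean for choroid plexus markers, adding log2 library size as a covariate, and testing the lists for the diet-by-sex contrast and for diet in males and in females. A count was held to have moved where it differed by more than 1.5 times. Each count was also computed in 100 splits of the libraries, the real one included, in which the factor was permuted within strata of the other factors and cohort.

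The calling steps were tested on simulated counts with the design, library sizes and dispersions of these data and 200 changed genes in each simulated table. For genotype, edgeR recovered 42 of 50 genes changed 1.2-fold, 42 of 50 changed 1.3-fold, 50 of 50 changed 1.5-fold and 49 of 50 changed 2-fold. All had the right sign, and 16 unchanged genes were called falsely. The smallest simulated change was 0.26 log2, above the median of 0.12 log2 among the genes called for genotype, so recovery of smaller changes was not tested. For the diet-by-sex contrast it recovered 19 of 50 changed 1.2-fold and 45 of 50 changed 2-fold, with 6 false calls. A list of 24 simulated genes raised 1.2-fold passed camera, and 0 of the unchanged lists did. Simulated genes were independent of each other, so these lists do not test the preset correlation.

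Library totals of 13.9 to 31.4 M counts set the precision, and counts do not separate molecules from PCR copies. The gene-wise tests use the spread between libraries, which includes counting error. Rows for RT1 genes, C4a and C4b, Scd and Scd2, and Ddx3 and Ddx3y can share reads between near-identical copies. Rows for App and Prnp can hold reads of the introduced human genes or their promoter-linked sequence. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Cohort 2 minus cohort 1 gave 11 called genes, 9 higher and 2 lower, and leaving out any library other than replicate 20 of female_wildtype_chow moved that count by more than 1.5 times, to between 0 and 43.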

Results

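Gene expression was counted in 30 polyA libraries of dorsal hippocampus from TgF344-AD rats, labelled alzheimer, and from wildtype rats, on standard chow or a western diet. TgF344-AD is a transgenic rat line that carries mutated human APP driven by the mouse prion promoter. Libraries keep the running number of their title as replicate number. The male groups were male_wildtype_chow (replicates 4, 7, 26 and 29), male_wildtype_western (2, 5, 24 and 27), male_alzheimer_chow (3, 8, 25 and 30) and male_alzheimer_western (1, 6, 23 and 28). The female groups were female_wildtype_chow (replicates 9, 13, 15 and 20), female_wildtype_western (12, 17 and 22), female_alzheimer_chow (10, 14, 16 and 19) and female_alzheimer_western (11, 18 and 21). Cohort 1 held 14 libraries and cohort 2 held 16. Totals ran from 13.9 to 31.4 M counts (M for mega) with a median of 17.8 M, and the deepest library was female_alzheimer_chow replicate 10. The mean total was 19.5 ± 3.97 M in 14 female and 17.4 ± 1.84 M in 16 male libraries (SD). Between 13464 and 14051 of 17455 genes had a count in each library, and 12547 genes were tested.

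Sex-linked genes matched the sex labels in all 30 libraries. Xist (row LOC100911498), the RNA that silences an X chromosome, stood at 579 ± 62.3 CPM in females (SD, n = 14) and at 0.703 ± 0.266 CPM in males (n = 16). The Y-linked gene Eif2s3y stood at 71.9 ± 4.22 CPM in males and at 0.0843 ± 0.0629 CPM in females. App, the amyloid precursor gene, was at 3293 ± 76.3 CPM in alzheimer and 1672 ± 52.7 CPM in wildtype libraries (n = 15 each), with no overlap. The first principal component of log2 CPM held 13.2% of the variance, and sex accounted for 82.0% of it. The second component held 6.70%, with 47.5% of it along genotype. Sex-linked rows such as Xist and Eif2s3y were included in these components, and their share was not measured. The common biological coefficient of variation was 6.27%, so small changes were detectable in the pooled comparisons.

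Genotype changed the expression of 1007 genes, with 519 higher and 488 lower in alzheimer than in wildtype, averaged over sex and diet with 15 libraries per side. Most changes were small. Their median size was 0.12 log2, 27 genes changed more than 1.5-fold and 10 more than 2-fold. App was higher by 0.98 ± 0.017 (adjusted p = 1.65e-30) and Sh3glb2, an endophilin family member with roles in membrane curvature, by 1.42 ± 0.025 (adjusted p = 1.79e-30), each in 15 of 15 libraries. The prion protein gene Prnp was higher by 0.17 ± 0.020 (adjusted p = 1.87e-07). Counts do not separate rat from human reads for App, or reads of promoter sequence shared with Prnp. Galnt5, a glycosyltransferase, was near its detection limit in wildtype at 0.204 ± 0.145 CPM and reached 2.19 ± 0.431 CPM in alzheimer, a log2 fold change of 3.37 ± 0.21 (adjusted p = 1.63e-13). Gdf3, a TGF-beta family ligand, went from 0.0631 ± 0.0659 to 1.3 ± 0.688 CPM, by 4.31 ± 0.39 (adjusted p = 1.86e-09).

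The MHC class II gene RT1-Ba rose from 1.29 ± 0.645 to 3.31 ± 1.40 CPM (log2 fold change 1.38 ± 0.17, adjusted p = 1.07e-06). RT1-Da, another class II gene, rose by 1.21 ± 0.16 and Cd74, the invariant chain that accompanies class II molecules, by 0.83 ± 0.087, all 3 in 15 of 15 libraries. Abracl rose by 0.70 ± 0.046, the splicing factor Rbm20 by 0.74 ± 0.14, the relaxin-3 receptor Rxfp3 by 0.73 ± 0.091, and Kcns1, a modifier of potassium channels, by 0.66 ± 0.072. Among the genes that fell, the zinc finger gene Zfp347 fell from 7.29 ± 0.940 to 2.33 ± 0.554 CPM (log2 fold change −1.64 ± 0.10, adjusted p = 1.28e-13). The activin antagonist Fst fell from 5.19 ± 1.13 to 2.28 ± 0.685 CPM (−1.16 ± 0.12, adjusted p = 2.76e-08). Smaller falls were seen for the kinase Plk3 (−0.60 ± 0.073), the channel subunit Asic4 (−0.60 ± 0.084), the lectin Cd22 (−0.57 ± 0.10) and Col18a1, a basement membrane collagen (−0.47 ± 0.056). With cohort 1 alone 72 genes were called, and 66 of them had the same sign in cohort 2. Cohort 2 alone gave 573 called genes, 550 of them with the same sign in cohort 1, and 57 were called in both. Of the genotype genes named here and below, Rbm20, Mbp and Mx2 were called in neither cohort alone. Cohort 1 alone also did not call Cd22, C3, C1qa, Gfap, Fasn, Acaca, Cox6a1, Cox8a, Cox4i1 or Nsf. Nor did it call S100b, Slc1a3, Cldn5, Rgs5, Abcc9, Wfs1, Apoe, Ifi27 or Stat2. In cohort 1 alone the adjusted p of these genes ran from 0.103 to 0.771, with the sign unchanged. DESeq2 and limma-voom counts lay within 1.5 times the edgeR count, as did each count with 1 library left out.

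**Figure D1:**
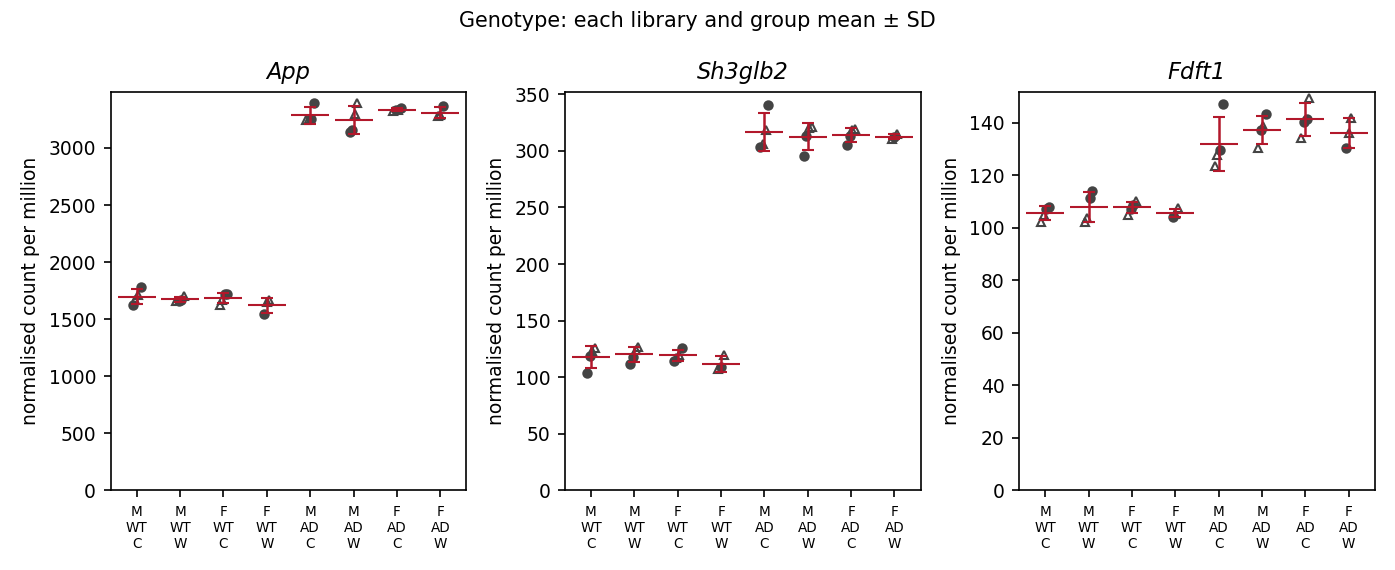
CPM of App, Sh3glb2 and Fdft1 in each library of the 8 groups; filled circles are cohort 1, open triangles cohort 2, and red marks show mean ± SD. App and Sh3glb2 were higher in alzheimer than in wildtype libraries in each sex and diet, and Fdft1 averaged 137 against 107 CPM.

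Cholesterol biosynthesis genes rose together in alzheimer. Of 24 tested members 20 were higher and 0 lower over all genes, and 23 were higher when adjusted over the list alone, with a median of 0.20. The list passed camera (adjusted p = 3.63e-45) and passed with an estimated correlation (adjusted p = 7.87e-07), and its mean was higher in 15 of 15 libraries. Stard4, a sterol carrier, rose from 17.7 ± 1.37 to 24.2 ± 2.39 CPM (log2 fold change 0.44 ± 0.044, adjusted p = 1.30e-08). Fdft1, which makes squalene, rose from 107 ± 3.36 to 137 ± 7.39 CPM (0.36 ± 0.024, adjusted p = 5.10e-13). Acat2 rose by 0.37 ± 0.036 and Hmgcs1, an early enzyme of the pathway, by 0.25 ± 0.025. Fatty acid synthesis genes passed camera as higher with 5 of 16 members called (median 0.018, adjusted p = 0.00627), but not with an estimated correlation (adjusted p = 0.202) or in cohort 2 alone (adjusted p = 0.0696). Adjusted over the list alone 5 members were higher and 1 lower. The called members included the citrate lyase Acly (0.17 ± 0.016), the desaturase Scd (0.25 ± 0.036), the fatty acid synthase Fasn (0.14 ± 0.018) and the carboxylase Acaca (0.15 ± 0.027).

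**Figure D2:**
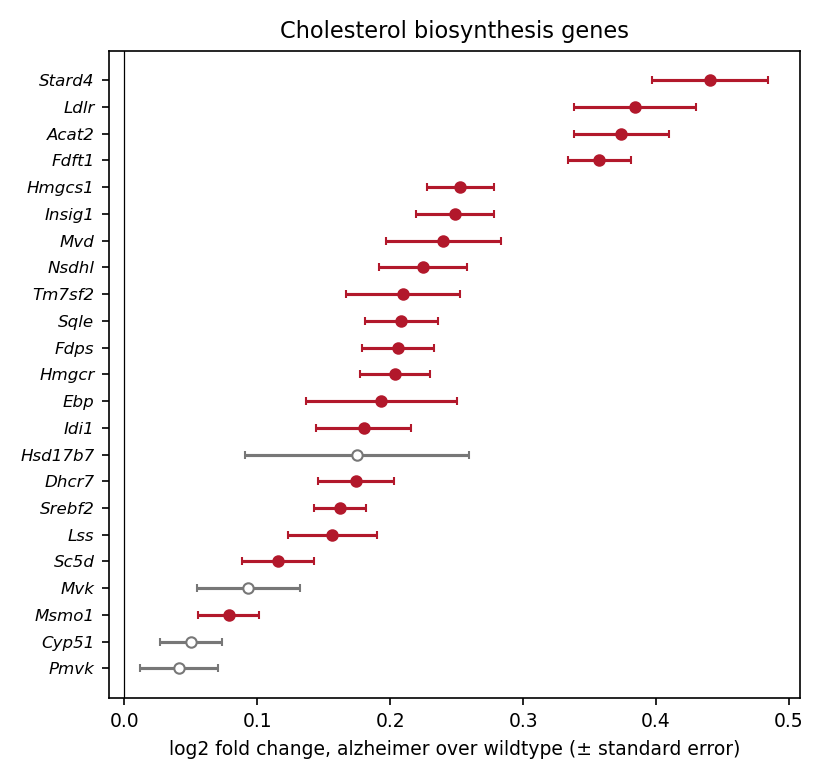
Log2 fold change, alzheimer minus wildtype, ± standard error for 23 of the 24 tested cholesterol biosynthesis genes; filled red marks have an adjusted p under 0.05. Of the 24 genes 20 were called, and Stard4 stood at 0.44.

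Nuclear genes of oxidative phosphorylation fell together in alzheimer by small amounts. Of 72 tested members 27 were lower and 0 higher, and 43 were lower when adjusted over the list alone, with a median of −0.065. The list passed camera (adjusted p = 2.19e-17) and was lost with an estimated correlation (adjusted p = 0.202). It passed downward by fry (adjusted p = 0.000527) and by camera with 2 surrogate variables (adjusted p = 9.41e-15). In cohort 2 alone it also passed downward (adjusted p = 2.17e-12), and in cohort 1 alone it pointed downward. The camera fits with surrogate variables and by cohort kept the preset correlation of 0.01, against an estimate of 0.287. They therefore do not answer the loss with an estimated correlation. Its mean was lower in 14 of 15 libraries. The cytochrome oxidase subunit Cox6a1 fell from 411 ± 16 to 377 ± 15.5 CPM (log2 fold change −0.13 ± 0.020, adjusted p = 4.80e-05), Cox8a fell by 0.13 and Cox4i1 by 0.10 on the log2 scale, and the complex I subunit Ndufb9 by 0.13. The amyloid and tau list passed as higher (adjusted p = 5.84e-17, and adjusted p = 2.71e-07 with an estimated correlation) although its median over 15 members was 0.020. App and Prnp were among its called members, and 4 were higher and 1 lower when adjusted over the list alone. Both rows can hold reads of the introduced genes or their promoter-linked sequence. The passing of this list can therefore not be taken as a change of the rat genes. Presynaptic genes rose (7 of 20 called, 12 adjusted over the list alone, median 0.063, adjusted p = 4.38e-05), with an adjusted p = 0.403 with an estimated correlation. They passed upward by fry (adjusted p = 0.0120) and by camera with 2 surrogate variables (adjusted p = 0.000305). In cohort 2 alone they also passed upward (adjusted p = 4.76e-05), and in cohort 1 alone they pointed upward. The camera fits with surrogate variables and by cohort kept the preset correlation, against an estimate of 0.351. The fusion ATPase Nsf rose by 0.085 ± 0.021.

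Complement genes fell in alzheimer. Of 16 tested members 6 were lower and 0 higher, 7 were lower when adjusted over the list alone, and the median was −0.14. Camera gave an adjusted p = 4.38e-05, and an adjusted p = 0.202 with an estimated correlation. The list passed downward by fry (adjusted p = 0.00345) and by camera with 2 surrogate variables (adjusted p = 0.00611). In cohort 2 alone it also passed downward (adjusted p = 1.51e-05), and in cohort 1 alone it pointed downward. The camera fits with surrogate variables and by cohort kept the preset correlation, against an estimate of 0.214. Itgam, a complement receptor subunit of microglia, fell from 21.7 ± 1.93 to 16.5 ± 1.60 CPM (log2 fold change −0.40 ± 0.049, adjusted p = 7.43e-07) and C3, the central component, from 59.4 ± 7.0 to 48.6 ± 6.75 CPM (−0.29 ± 0.049, adjusted p = 0.000209). C1qa fell by 0.17 on the log2 scale. Other microglial lists did not pass: homeostatic microglia had 3 of 14 members lower (adjusted p = 0.0906), and disease-associated microglia had 2 higher and 2 lower of 21 (adjusted p = 0.631), with a median of −0.0051 and a mean of 0.061. Antigen presentation had 4 of 14 members higher and 3 lower, with a median of −0.028, a mean of 0.32 and an upward camera test (adjusted p = 0.0832, and adjusted p = 0.403 with an estimated correlation). It passed upward in cohort 2 alone (adjusted p = 0.00694), with 2 surrogate variables (adjusted p = 0.0190) and by fry (adjusted p = 0.0185), and pointed upward in cohort 1 alone. The camera fits among these kept the preset correlation. Gfap, the astrocyte filament gene, was at 1471 ± 108 against 1308 ± 116 CPM (log2 fold change 0.17 ± 0.032, adjusted p = 0.000511), while reactive astrocytes as a list had 2 members higher and 1 lower of 21 (adjusted p = 0.811). Trem2 stood at 9.60 ± 1.36 and 9.67 ± 0.939 CPM (−0.021 ± 0.056, adjusted p = 0.878) and C4b at 2.10 ± 0.709 and 2.26 ± 0.865 CPM (−0.10 ± 0.16, adjusted p = 0.786). Cst7 was below the filter, at 0.0807 ± 0.0746 and 0.0717 ± 0.124 CPM.

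Several cell type lists were lower in alzheimer under camera with the preset correlation, none of them with an estimated one. Endothelial genes had 4 of 17 members lower (7 adjusted over the list alone, median −0.10, adjusted p = 0.00173, and adjusted p = 0.403 with an estimated correlation), among them the tight junction gene Cldn5 at −0.11 ± 0.027. Astrocyte genes had 2 of 15 lower, S100b at −0.13 ± 0.021 and the glutamate transporter Slc1a3 at −0.12 ± 0.028 (4 adjusted over the list alone, median −0.064, adjusted p = 0.00642, and adjusted p = 0.431 with an estimated correlation). CA1 pyramidal neuron genes had 2 of 7 lower (5 adjusted over the list alone, median −0.11, adjusted p = 0.0161, and adjusted p = 0.431 with an estimated correlation), with Wfs1 at 745 ± 96.2 against 851 ± 62.8 CPM. Genes of pericytes, smooth muscle and meninges had 2 of 14 lower, Rgs5 at −0.24 ± 0.055 and Abcc9 at −0.33 ± 0.073 (3 adjusted over the list alone, median −0.086, adjusted p = 0.0282, and adjusted p = 0.431 with an estimated correlation). Oligodendrocyte genes had 1 of 20 lower (0 adjusted over the list alone, median −0.062, adjusted p = 0.0197, and adjusted p = 0.749 with an estimated correlation). The call of that member, Mbp (−0.19 ± 0.059), ended in DESeq2 (adjusted p = 0.0718) and without replicate 2, 3, 4, 5, 6, 9, 14, 15, 17, 18, 19, 23, 25 or 29 (adjusted p from 0.0506 to 0.0883). Lipid transport genes had 3 of 16 lower (5 adjusted over the list alone, median −0.023, adjusted p = 0.0321, and adjusted p = 0.403 with an estimated correlation), among them the lipid carriers Apoe, from 4327 ± 286 to 3986 ± 171 CPM, and Apoc1, at −0.28 ± 0.039. Interferon response genes had Stat2 higher (0.12 ± 0.032), Ifi27 and Mx2 lower (−0.11 ± 0.023 and −0.15 ± 0.040) and 1 higher and 4 lower of 20 when adjusted over the list alone (median −0.13, adjusted p = 0.0419, and adjusted p = 0.431 with an estimated correlation). The call of Mx2 ended without replicate 17 (−0.11, adjusted p = 0.0610) and with 2 surrogate variables (−0.13, adjusted p = 0.0866). By fry the endothelial and lipid transport lists passed downward (adjusted p = 0.0185 and 0.0183). The astrocyte, CA1 and interferon lists did not pass fry (each adjusted p = 0.0586), nor did the pericyte (0.0719) and oligodendrocyte lists (0.415). With 2 surrogate variables the oligodendrocyte, pericyte, lipid transport and interferon lists no longer passed camera (adjusted p = 0.516, 0.223, 0.302 and 0.223). In cohort 1 alone the astrocyte, pericyte, lipid transport and interferon lists did not pass (adjusted p = 0.481, 0.137, 0.266 and 0.361), and in cohort 2 alone the oligodendrocyte list did not (adjusted p = 0.0601). In all, 13 of 37 lists passed, and 8 of 100 splits of the libraries, the real one included, passed as many. Markers of the neighbouring choroid plexus had a median of −0.065 (adjusted p = 0.615) and ependymal markers one of −0.29 (adjusted p = 0.0572).

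The genotype difference was also tested within each diet and each sex, to show whether it held there. On chow 113 genes were called (68 higher, 45 lower) and on the western diet 398 (189 higher, 209 lower). Both diets shared 49 higher and 31 lower genes, against 1.02 and 0.75 for independent lists, and 0 genes had opposite signs. App was higher by 0.97 ± 0.023 on chow and 0.99 ± 0.025 on the western diet, and Sh3glb2 by 1.41 ± 0.034 and 1.43 ± 0.037. Fst was lower by −1.33 ± 0.17 and −1.0 ± 0.17, and RT1-Ba higher by 1.62 ± 0.25 and 1.13 ± 0.23, although DESeq2 gave no adjusted p for Fst and RT1-Ba on the western diet. Of the 113 genes called on chow, 110 had the same sign on the western diet, and 384 of the 398 called on the western diet had the same sign on chow. In males 157 genes were called (86 higher, 71 lower) and in females 322 (155 higher, 167 lower), with 58 higher and 30 lower genes shared against 1.06 and 0.95 for independent lists. RT1-Da was higher by 1.5 ± 0.24 in males and by 0.92 ± 0.22 in females (adjusted p = 0.0167). The female call of RT1-Da ended without replicate 11, 17 or 22 (adjusted p = 0.0732, 0.0592 and 0.0696). Larger counts in females or on the western diet do not show a difference, and the tests of that difference called 0 genes.

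Leaving out 1 library moved some of these counts by more than 1.5 times. The western count was 229 without replicate 17, 259 without 18 and 252 without 22. The male count was 98 without replicate 3, 97 without 4, 311 without 8, 99 without 25 and 100 without 29. The female count was 208 without replicate 11, 191 without 15, 164 without 17 and 198 without 22. On chow, cohort 1 alone gave 29 called genes and cohort 2 alone 43, all with the same sign in the other cohort. On the western diet cohort 2 alone gave 185, of which 176 had the same sign in cohort 1. In males it gave 107, of which 89 had the same sign. In females it gave 141 of the genes tested in both cohorts, of which 132 did. For females and the western diet the cohort 1 values rest on 1 library in each female western group.

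Whether the genotype effect depends on diet or sex was tested by interaction terms, and 0 genes passed in edgeR, DESeq2 or limma-voom for genotype by diet, genotype by sex or all 3 factors. At an unadjusted p under 0.05 there were 446, 528 and 623 genes. The smallest p for genotype by diet belonged to Ddx3y at 2.06 ± 0.48, a row at about 0.5 CPM, Tigd5 at 0.50 ± 0.12 and the potassium channel gene Kcnj16 at −0.39 ± 0.099, which did not pass. For genotype by sex they were Cenpn (0.78 ± 0.17), Fam167a (1.93 ± 0.46) and Ociad2 (−0.26 ± 0.065), and for all 3 factors Ccdc12 (0.68 ± 0.15), Grm4 (1.0 ± 0.23) and Rec114 (−4.81 ± 1.26), none past the threshold. As a list, endothelial genes had a lower diet effect in alzheimer than in wildtype, with 0 of 17 log2 values above 0 and a median of −0.16 (adjusted p = 1.04e-08, and adjusted p = 0.185 with an estimated correlation). Adjusted over the list alone 3 members passed, and values included Mfsd2a, a lipid transporter of the blood-brain barrier, at −0.29 ± 0.093 and Cldn5 at −0.16 ± 0.054. The same held at the preset correlation for 6 lists: astrocytes (median −0.081, adjusted p = 0.000274, and adjusted p = 0.611 with an estimated correlation), complement (−0.14, adjusted p = 0.00211, and adjusted p = 0.611 with an estimated correlation) and glycolysis (−0.023, adjusted p = 0.0300, and adjusted p = 0.611 with an estimated correlation). The others were pericytes, smooth muscle and meninges (−0.14, adjusted p = 0.0300, and adjusted p = 0.611 with an estimated correlation), oligodendrocyte precursors (−0.10, adjusted p = 0.0399, and adjusted p = 0.664 with an estimated correlation) and nuclear oxidative phosphorylation (−0.024, adjusted p = 0.0411, and adjusted p = 0.859 with an estimated correlation). No member of these 6 lists passed over all genes or adjusted over the list alone, and fry passed 0 lists. Of 100 splits 49 passed at least 7 lists. In cohort 1 alone the complement list and that of pericytes, smooth muscle and meninges turned upward (adjusted p = 0.574 and 0.528), and in cohort 2 alone oxidative phosphorylation turned upward (adjusted p = 0.318).

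**Figure D3:**
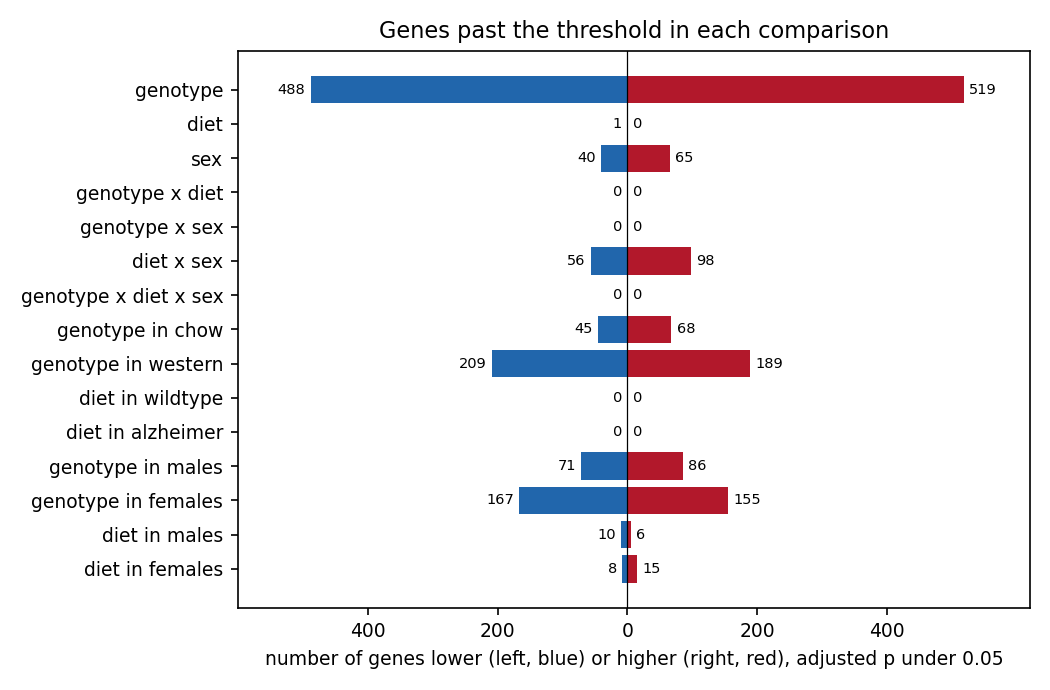
Number of genes called higher (right) and lower (left) at an adjusted p under 0.05 in each contrast. Genotype called 519 higher and 488 lower genes, while diet called 0 higher and 1 lower.

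The western diet was compared with chow over both sexes and genotypes to show its effect on the hippocampus, and 1 gene passed. Rbm3, an RNA-binding protein induced by cold, fell from 91.3 ± 7.53 CPM on chow (n = 16) to 78.5 ± 9.87 CPM on the western diet (n = 14), a log2 fold change of −0.24 ± 0.040 (adjusted p = 0.00974), lower in 13 of 14 libraries. The lipogenic regulator Thrsp stood at −0.19 ± 0.043 (adjusted p = 0.217), Scd at −0.11 ± 0.036 (adjusted p = 0.822), the chaperone Hspa5 at 0.061 ± 0.027 (adjusted p = 0.861) and Cd74 at 0.28 ± 0.088 (adjusted p = 0.822), none of which passed. At an unadjusted p under 0.05 there were 696 genes, and DESeq2 called 3. The count was 2 without replicate 3, 12 or 30. Rbm3 stood at −0.25 (adjusted p = 0.0628) without the 3 libraries highest in choroid plexus markers and at −0.20 (adjusted p = 0.826) in cohort 2 alone. Cohort 1 alone called 19 genes, of which 5 had the same sign in cohort 2, and cohort 2 alone called 0. Across genes the log2 values of both cohorts correlated at −0.020, although genes are not independent replicates.

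No gene passed for diet in wildtype rats or in alzheimer rats in edgeR, with 653 and 488 genes at an unadjusted p under 0.05. For wildtype DESeq2 and limma-voom called 0 as well, while cohort 1 alone called 38, of which 13 had the same sign in cohort 2. For alzheimer DESeq2 called 3 and limma-voom 0, and the count was 3 without replicate 3 or 16, 2 without 21 and 1 without 28. The smallest p in alzheimer belonged to Rbm3 (−0.30 ± 0.056, adjusted p = 0.0893), Adgrf5, an adhesion receptor of endothelium, (−0.31 ± 0.061, adjusted p = 0.105) and Thrsp (−0.28 ± 0.060, adjusted p = 0.271). In wildtype it belonged to Tigd5 (−0.43 ± 0.087, adjusted p = 0.288), Kcnj16 (0.29 ± 0.069, adjusted p = 0.935) and Rnf227 (−0.23 ± 0.057, adjusted p = 0.935). As 0 genes were called, both genotypes shared 0 calls. Among the lists, 5 passed camera for diet over all libraries and 0 with an estimated correlation or with fry, and no member was called. Chaperone and unfolded protein genes were higher, with 19 of 22 values above 0 and a median of 0.036 (adjusted p = 0.000706, and adjusted p = 0.371 with an estimated correlation). Disease-associated microglia (median 0.035, adjusted p = 0.0157), activity-regulated genes (0.034, adjusted p = 0.0157) and astrocytes (0.043, adjusted p = 0.0193) were higher and fatty acid synthesis lower (−0.029, adjusted p = 0.0157). With an estimated correlation these had an adjusted p = 0.371, 0.838, 0.838 and 0.371. Adjusted over the list alone 2 fatty acid synthesis genes and 1 astrocyte gene were lower. Of 100 splits 71 passed at least 5 lists. Choroid plexus markers had a median of −0.089 between the diets (adjusted p = 0.0748).

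Females were compared with males over both genotypes and diets, and 105 genes were called, with 65 higher and 40 lower in 14 female than in 16 male libraries. X-linked genes known to escape inactivation were higher in females, with 3 of 4 tested called, Xist and 2 of the other 3 genes (with Xist in the list, camera adjusted p = 7.47e-283, and adjusted p = 1.06e-17 with an estimated correlation). Eif2s3 was at 226 ± 11.5 against 141 ± 6.13 CPM and Ddx3x at 359 ± 13.8 against 288 ± 15.3 CPM, while Usp9x was at −0.016 ± 0.024 (adjusted p = 0.815). The row named Ddx3 had the pattern of a Y-linked gene, at 54.9 ± 4.08 CPM in males and 0.112 ± 0.126 CPM in females, and the row named Ddx3y, at 0.508 ± 0.236 and 0.536 ± 0.354 CPM, did not, so these symbols may stand for other loci than they name. Gpr34, an X-linked microglial receptor, was at 27.9 ± 4.75 against 17.6 ± 2.43 CPM (log2 fold change 0.65 ± 0.055, adjusted p = 4.64e-10, 14 of 14 libraries), and the X-linked Pbdc1 was higher by 0.36 ± 0.040. Antigen presentation genes were higher, with 6 of 14 called, 9 adjusted over the list alone and a median of 0.17 (adjusted p = 1.50e-06, and adjusted p = 0.00787 with an estimated correlation), in 14 of 14 libraries. Cd74 was at 15.6 ± 5.40 against 9.51 ± 3.40 CPM (0.73 ± 0.087, adjusted p = 2.04e-06), and RT1-Da was higher by 0.87 ± 0.16. The nucleolar gene Dkc1 was lower by −0.25 ± 0.040 (adjusted p = 0.000669) and the anticoagulant Tfpi by −0.21 ± 0.036 (adjusted p = 0.00204), each in 14 of 14 libraries.

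Other lists that passed for sex at the preset correlation were lost with an estimated one. They were higher in females: homeostatic microglia (1 called of 14, 4 adjusted over the list alone, median 0.074, adjusted p = 0.00204, and adjusted p = 0.324 with an estimated correlation), complement (2 of 16, 6 adjusted over the list alone, 0.10, adjusted p = 0.0283, and adjusted p = 0.656 with an estimated correlation) and astrocytes (1 of 15, 2 adjusted over the list alone, 0.058, adjusted p = 0.0283, and adjusted p = 0.656 with an estimated correlation). Disease-associated microglia had 2 members higher and 1 lower of 21, 4 and 2 adjusted over the list alone (median 0.087, adjusted p = 0.0283, and adjusted p = 0.339 with an estimated correlation). Ependyma had 4 of 7 adjusted over the list alone and 0 over all genes (0.28, adjusted p = 0.0418, and adjusted p = 0.656 with an estimated correlation), and oligodendrocytes 1 of 20 and 0 (0.077, adjusted p = 0.0418, and adjusted p = 0.831 with an estimated correlation). With 2 surrogate variables oligodendrocyte genes turned lower in females (adjusted p = 7.49e-06). Homeostatic microglia (adjusted p = 0.0576) and disease-associated microglia (adjusted p = 0.498) no longer passed there, while 6 lists passed in all. Markers of thalamus, choroid plexus and neocortex, which border the dissected tissue, had medians of 0.21, 0.11 and 0.092 (adjusted p = 0.0679, 0.273 and 0.0618). The neocortex markers were higher in females in 13 of 14 libraries, with 6 of 12 members higher adjusted over the list alone, and passed fry (adjusted p = 0.000493). Of 100 splits 45 passed at least 8 lists.

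The count of genes called for sex depended on single libraries. It was 66 without replicate 2 or 3, 68 without 6, 55 without 7, 17 or 27, 181 without 9, 40 without 10, 19 without 11, 49 without 13, 67 without 15 and 170 without 18. Without the 3 libraries highest in choroid plexus markers, replicate 11 among them, it was 23, with library size as a covariate 34 and with 2 surrogate variables 36, where RT1-Da was not called (0.72, adjusted p = 0.0939). Cohort 1 alone called 145 genes, 109 of them with the same sign in cohort 2, and cohort 2 called 17, 16 of them with the same sign in cohort 1. Gpr34, Cd74, Dkc1 and Tfpi stayed called with each library left out.

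The effect of the western diet differed between the sexes for 154 genes, 98 with a higher value in females and 56 with a lower one. The fitted diet effect of all 154 had opposite signs in males and females. Choosing genes by this difference favours opposite signs where the mean diet effect is small, so the signs are no separate evidence. Of the 154 genes, 16 were called for diet in males and 19 in females, so for most no effect within a sex was established. Pdk4, a kinase that shuts down pyruvate dehydrogenase, fell in males from 7.24 ± 2.95 CPM on chow to 2.58 ± 0.863 CPM on the western diet (n = 8 each) and rose in females from 3.09 ± 0.95 (n = 8) to 6.93 ± 2.10 CPM (n = 6). Its diet effect was 2.66 ± 0.33 log2 higher in females (adjusted p = 1.37e-05). The stress kinase Sgk1 went from 221 ± 57.4 to 118 ± 33.9 CPM in males and from 135 ± 47.3 to 214 ± 37.5 CPM in females, a difference of 1.61 ± 0.23 (adjusted p = 0.000100). Ddit4, an inhibitor of mTOR signalling, went from 145 ± 18 to 95.9 ± 20.04 CPM and from 93.0 ± 16.4 to 136 ± 11.6 CPM (1.14 ± 0.14, adjusted p = 1.37e-05). The cell cycle inhibitor Cdkn1a (1.25 ± 0.20), the NF-kappaB inhibitor Nfkbia (1.04 ± 0.19) and Errfi1 (0.72 ± 0.097) also had a higher diet effect in females. A lower one was seen for Dll4, a Notch ligand of endothelium (−1.12 ± 0.18, adjusted p = 0.000376), the endothelial transcription factor Sox18 (−0.97 ± 0.14) and the homeobox gene Hhex (−1.04 ± 0.22). On chow the male mean of Pdk4, Sgk1 and Ddit4 lay above the female mean, and on the western diet it lay below. The calls of Nfkbia (0.45, adjusted p = 0.399), Sox18 (−0.70, adjusted p = 0.0884) and Hhex (−1.10, adjusted p = 0.125) ended with 2 surrogate variables, although the log2 value of Hhex did not shrink.

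**Figure D4:**
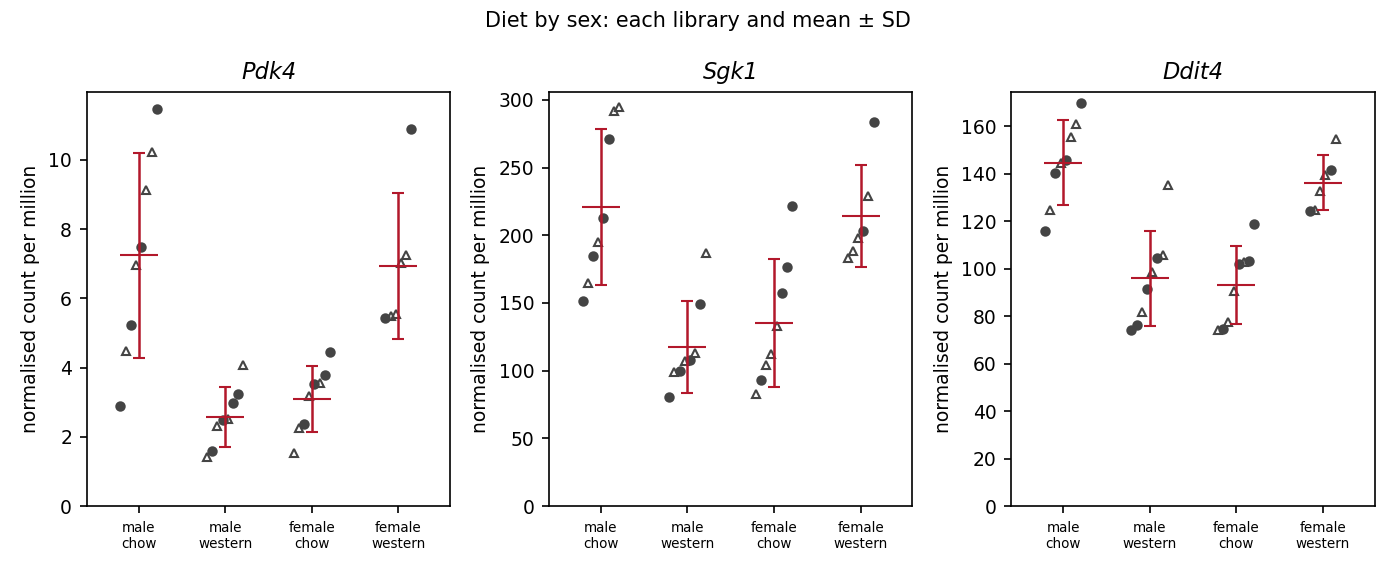
CPM of Pdk4, Sgk1 and Ddit4 in each library by sex and diet; filled circles are cohort 1, open triangles cohort 2, and red marks show mean ± SD. Ddit4 averaged 145 and 95.9 CPM in males on chow and western diet, and 93.0 and 136 CPM in females.

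Diet alone called 16 genes in males (6 higher, 10 lower) and 23 in females (15 higher, 8 lower). Of the 16 male genes 0 had the same sign in females, and 5 genes were called in both sexes, all with opposite signs, against 0.029 for independent lists. In males Pdk4 (−1.49 ± 0.23, adjusted p = 0.00153), Sgk1 (−0.92 ± 0.16, adjusted p = 0.00345), Cdkn1a (−0.76 ± 0.14, adjusted p = 0.010) and Ddit4 (−0.60 ± 0.096, adjusted p = 0.00230) fell, and Dll4 (0.65 ± 0.12, adjusted p = 0.010) and Spry2, a brake on growth factor signalling, (0.28 ± 0.040, adjusted p = 0.000596) rose, each in 8 of 8 libraries. In females Rbm3 fell from 91.4 ± 8.18 to 69.9 ± 7.27 CPM (−0.38 ± 0.059, adjusted p = 0.00299), while Pdk4 (1.17 ± 0.24, adjusted p = 0.0346) and Ddit4 (0.54 ± 0.10, adjusted p = 0.0239) rose, each in 6 of 6 libraries. The female call of Ddit4 ended without replicate 9, 12, 15, 18, 19 or 22 (adjusted p from 0.0582 to 0.116) and that of Pdk4 without 9, 10, 12, 15, 18, 19, 21 or 22 (from 0.0503 to 0.185). With 2 surrogate variables 0 genes were called in males and 6 in females, and cohort 2 alone called 0 and 2. In neither sex was a gene called in both cohorts taken alone. Neither cohort alone called Pdk4, Sgk1, Cdkn1a or Dll4 in males, or Pdk4 or Ddit4 in females. Cohort 2 alone also did not call Ddit4 or Spry2 in males or Rbm3 in females.

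Genes induced by glucocorticoids, the stress hormones of the adrenal gland, made up the list with the smallest camera p for a difference in diet effect between the sexes. Of 14 members 8 had a higher diet effect in females and 0 a lower one, 9 when adjusted over the list alone, with a median of 0.61 (camera adjusted p = 4.28e-25, and adjusted p = 0.0253 with an estimated correlation). The median fell to 0.235 with 2 surrogate variables, where the list still passed camera at the preset correlation (adjusted p = 1.07e-13). In males 6 members fell, 9 adjusted over the list alone (median −0.35, adjusted p = 8.38e-20, and adjusted p = 0.0368 with an estimated correlation). In females 3 members rose, 7 adjusted over the list alone (median 0.26, adjusted p = 4.28e-13), and the list was lost with an estimated correlation (adjusted p = 0.169). Not every member moved: Fkbp5, a chaperone of the glucocorticoid receptor, had a difference of 0.091 ± 0.073 (adjusted p = 0.606). Disease-associated microglia genes were higher on the western diet in males (median 0.065, adjusted p = 1.32e-05, and adjusted p = 0.0368 with an estimated correlation) with 0 members called over all genes and 1 adjusted over the list alone, but did not pass in cohort 2 alone (adjusted p = 0.104). Oligodendrocyte genes were also higher on the western diet in males at the preset correlation (median 0.11, adjusted p = 0.00620, and adjusted p = 0.691 with an estimated correlation), with 0 of 20 members called, and pointed down in cohort 2 alone (adjusted p = 0.150). Their diet effect was lower in females than in males (median −0.19, adjusted p = 0.00474, and adjusted p = 0.665 with an estimated correlation), although the 1 called member was higher. The lists for these 3 contrasts were tested after the data were seen.

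**Figure D5:**
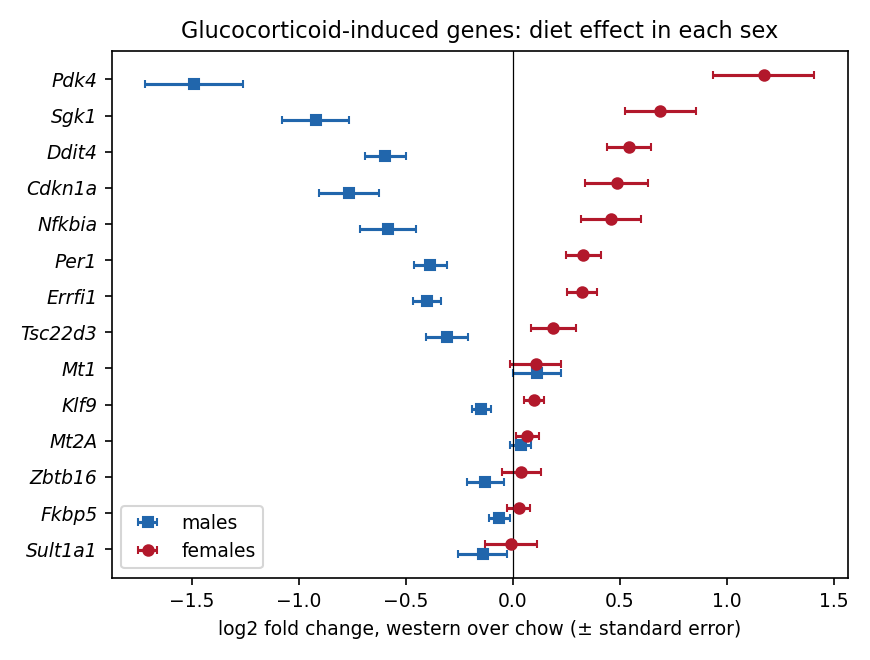
Log2 fold change, western minus chow, ± standard error for the 14 glucocorticoid-induced genes in males (blue squares) and females (red circles). Pdk4 stood at −1.49 in males and 1.17 in females.

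Endothelial genes had a lower diet effect in females than in males, with 3 of 17 members called, 10 adjusted over the list alone and a median of −0.22 (adjusted p = 5.43e-08, and adjusted p = 0.140 with an estimated correlation). In females 0 of 17 values lay above 0 (median −0.13, adjusted p = 3.44e-08, and adjusted p = 0.169 with an estimated correlation), with 7 lower when adjusted over the list alone. Insulin signalling genes had a higher diet effect in females (1 of 26 called, median 0.11, adjusted p = 5.47e-05, and adjusted p = 0.140 with an estimated correlation), as did postsynaptic genes (1 of 21, 8 adjusted over the list alone, 0.10, adjusted p = 4.35e-06, and adjusted p = 0.267 with an estimated correlation). Nuclear oxidative phosphorylation had a lower one (0 of 72 called, 3 adjusted over the list alone, −0.076, adjusted p = 2.51e-11, and adjusted p = 0.267 with an estimated correlation). In all 12 lists passed for the difference between the sexes, 13 for males and 10 for females, and 16 of 100 splits passed at least 12 for the difference. Choroid plexus markers had a median of 0.040 in this contrast (adjusted p = 0.763).

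The count of 154 genes for the difference between the sexes was 249 without replicate 8, 79 without 12, 87 without 15 and 93 without 18, and 14 with 2 surrogate variables. Pdk4, Sgk1, Ddit4, Errfi1, Cdkn1a and Dll4 stayed called with each library left out. Cohort 2 alone called 32 genes, all with the same sign in cohort 1, where each female western group had 1 library. Cdkn1a (adjusted p = 0.0787) and Hhex (adjusted p = 0.258) were not called in cohort 2 alone, nor in cohort 1 alone. Cohort 1 alone also did not call Dll4, Sox18 or Nfkbia. In males the count was 9 without replicate 1, 10 without 5 or 30, 30 without 8, 25 without 14, 33 without 18 and 53 without 28. In females it was 10 without replicate 2 or 24, 9 without 4 or 10, 12 without 6 or 25, 1 without 9, 12, 15, 18 or 19, 36 without 14, 14 without 17, 8 without 21, 2 without 22 and 13 without 27. DESeq2 called 268 genes for the difference, 62 in males and 56 in females.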

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

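The tests of clock output genes for the sex-specific diet effect and of oligodendrocyte and astrocyte markers for the cholesterol genes, and the splits for the medians of single lists, were chosen after the results were seen, and leaving out choroid plexus libraries and library size as a covariate were added as settings then.

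Single libraries stood apart from their group of 4 in 5 of 72 groups over 12 quantities, where chance alone puts 1 in 20 groups apart, or 3.6 of 72. Female_alzheimer_chow replicate 10 had 31.4 M counts while the others of its group lay between 17 and 18.3 M. Male_alzheimer_chow replicate 3 had App at 3398 CPM (others 3243 to 3254 CPM) and a mean centred log2 value of 0.152 for cholesterol genes (others 0.0698 to 0.0784). Rbm3 was at 89.9 CPM in male_wildtype_western replicate 27 (others 86.5 to 86.9 CPM), and Sgk1 at 80.3 CPM in male_wildtype_western replicate 5 (others 107 to 113 CPM). No explanation was tested for these libraries.

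The diet effect differed between females and males for 154 genes by the interaction test. On the log2 scale the female effect minus the male one was 2.66 for Pdk4, 1.61 for Sgk1, 1.25 for Cdkn1a, 1.14 for Ddit4, 1.04 for Nfkbia, 0.72 for Errfi1 and 0.71 for Per1. It was −1.58 for Pomc, −1.12 for Dll4, −1.08 for Ier3, −1.04 for Hhex and −0.97 for Sox18. The interaction call of Pomc ended without female_wildtype_chow replicate 15 (adjusted p = 0.0517) and that of Ier3 without female_wildtype_western replicate 12 (adjusted p = 0.0529). Over their alternatives the adjusted p ran from 0.00124 to 0.265 for Pomc and from 0.00327 to 0.678 for Ier3.

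Genes induced by glucocorticoids had a median diet effect 0.61 log2 higher in females than in males, and 1 of 100 splits of the libraries, the real one included, gave as many called genes for this contrast, with 154 against 101 in the highest other split. Choroid plexus in the tissue is argued against by a median of 0.56 without the 3 libraries highest in its markers. Collection at different times of day stays open. The differences of the clock outputs Dbp and Nr1d1 with 2 standard errors added reached 0.33 at most, below the lower bound of 0.49 for Per1. However, Per1 is also on the glucocorticoid list. The clock list passed camera for the same contrast at the preset correlation (median 0.072, adjusted p = 0.00153) and was lost with an estimated one (adjusted p = 0.189). Variation between libraries within groups stays open, as the median fell to 0.235 with 2 surrogate variables, with 14 called genes left. An acute stress response at collection that differed between groups may account for it as well as a sex-specific response to diet; handling was not tested, and Fkbp5, another target, did not pass (0.091 log2).

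Cholesterol biosynthesis genes had a genotype median of 0.20 log2, and no other of the 100 splits came above 0.13 in size. More oligodendrocytes or astrocytes in the alzheimer tissue would raise their markers, but the larger of both medians was −0.062. Library size as a covariate left the median at 0.20. A response of cells to the genotype may be behind these genes, which is a hypothesis found on the same data. Which cell type carries it was not tested.

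Large changes of single genes between the genotypes, such as Sh3glb2, Galnt5 and Zfp347, might mark chromosome segments that differ between the lines. Of 23 genes changed more than 1.5-fold with a position in the GRCr8 order, MHC genes aside, 0 had another such gene within 20 tested genes, where random sets of like expression had a median of 2 and a 95th percentile of 4. These positions argue only against several of these genes sharing a segment within that window. A longer segment, segments with a single such gene each, or a segment of MHC genes could also give 0. Single variants and the site of the introduced genes were not tested. Reads of the human genes counted as rat App, at 0.98 log2, cannot be told apart from rat transcripts, because the table holds counts only.

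Other splits of the libraries tested whether chance can be excluded, with 100 splits per result, the real one included. For genotype 1 split gave as many genes (1007, highest other 323), for sex 1 (105, highest other 1), for genotype on chow 1 (113, highest other 108), on the western diet 1 (398, highest other 44), in females 1 (322, highest other 54) and in males 2 (157, highest other 420). For diet 3 splits gave at least 1 gene (highest other 4), for diet in males 3 gave at least 16 (highest other 156), for diet in females 1 gave at least 23 (highest other 15) and for cohort 1 gave at least 11 (highest other 7). Each of these counts was reached in fewer than 5 of 100 splits, with each contrast taken alone and no adjustment over the contrasts. For the 1 gene for diet, the 16 for diet in males and the 157 for genotype in males, another split gave more genes. Chance therefore stays open for these counts. For the others named here the real split gave the most genes. Why another split called 420 genes for genotype in males and another 156 for diet in males, more than the real counts, was not tested. The overlap of genotype calls on both diets was 80 genes (highest other 0), which decides nothing, because 0 of the other 99 splits had calls on both diets. For the contrasts with 0 called genes all 100 splits gave at least as many, which excludes nothing, and the highest other split gave 15 genes for genotype by diet, 1 for genotype by sex, 27 for all 3 factors, 96 for diet in wildtype and 3 for diet in alzheimer.

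The number of gene lists that passed camera at the preset correlation cannot be set apart from chance in any contrast. As many lists passed in 8 splits for genotype (13 lists, highest other 16), 71 for diet (5, highest other 20), 45 for sex (8, highest other 23), 49 for genotype by diet (7, highest other 17), 16 for diet by sex (12, highest other 16), 20 for diet in males (13, highest other 19) and 19 for diet in females (10, highest other 18). For single lists, only the cholesterol and glucocorticoid medians were compared over the splits, and both lists were chosen after the results were seen. The cholesterol median of 0.20 and the glucocorticoid median of 0.61 were each reached in size by 1 of 100 splits, the real one. The largest of the others were 0.13 and 0.41. Each median was compared with the same list in the other splits, not with the largest of all lists in each split. These splits therefore cannot decide whether a list picked for its strong result stands apart from chance.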

How the results depend on the processing

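Leaving out the 3 libraries highest in choroid plexus markers, adding library size as a covariate, and testing lists for diet by sex, diet in males and diet in females were chosen after the results were seen. No paired analysis was possible because the title numbers run from 1 to 30 and no 2 groups share a number. Counts of genes and lists stayed within 1.5 times of the reported value in 613 of the comparisons with an alternative, rose beyond it in 48 and fell beyond it in 117. For single genes the side of the threshold and the direction stayed in 6548 comparisons. The call ended in 432, a call appeared in 23 and the sign turned in 10. Of the 6548, 4860 left out 1 library and so shared all other libraries with the main fit. In cohort 2 alone 120 stayed, 46 calls ended and 4 signs turned. Contrasts and genes without a call in either fit are among those that stayed. These totals therefore do not measure how stable the calls are. The values below show where counts moved, and the cause was not tested. The cohort contrast has no value in fits without a cohort term or on 1 cohort alone. Cohort 1 alone has 1 library in each female western group, which limits its counts below.

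With cohort 1 alone, which has 14 of the 30 libraries, counts were 72 genes for genotype, 19 for diet, 12 for genotype by diet, 9 for genotype by sex, 12 for all 3 factors, 35 for diet by sex, 29 for genotype on chow, 40 on the western diet, 38 for diet in wildtype, 28 for genotype in males and 47 in females. With cohort 2 alone they were 573 for genotype, 0 for diet, 17 for sex, 32 for diet by sex, 43 for genotype on chow, 185 on the western diet, 141 in females, 0 for diet in males and 2 in females. Shared genotype calls on chow and western diet were 14 and 35 with either cohort alone. Without a filter on low counts, which tests more genes, counts were 254 for sex, 242 for diet by sex, 3 for diet in alzheimer, 71 for diet in males, 60 in females and 113 for cohort. DESeq2 gave 3 for diet, 241 for sex, 268 for diet by sex, 3 for diet in alzheimer, 247 for genotype in males, 62 for diet in males, 56 in females and 137 for cohort. Limma-voom gave 205 for sex and 5 for cohort. With 2 surrogate variables counts were 36 for sex, 14 for diet by sex, 264 for genotype on the western diet, 1 for diet in alzheimer, 0 for diet in males, 6 in females and 0 for cohort. Without the 3 choroid plexus libraries they were 0 for diet, 23 for sex, 103 for genotype in males, 188 in females and 0 for cohort. Library size as a covariate gave 34 for sex, 101 for diet by sex, 11 for diet in females and 0 for cohort. Without the cohort term diet in females gave 11. Fits on the stratum alone gave 95 for genotype in males and 45 for diet in females.

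Leaving out 1 library gave 817 to 1270 genes for genotype, 1 to 2 for diet, 19 to 181 for sex, 79 to 249 for diet by sex and 0 to 0 for genotype by diet, genotype by sex, all 3 factors and diet in wildtype. It gave 86 to 169 for genotype on chow, 229 to 471 on the western diet, 97 to 311 in males and 164 to 356 in females. For diet it gave 0 to 3 in alzheimer, 9 to 53 in males and 1 to 36 in females, and for cohort 0 to 43. Genotype calls shared between the diets were 68 to 116, and diet calls shared between the genotypes 0 to 0.

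Gene lists passed camera with an estimated correlation in 2 cases for genotype, 0 for diet, 2 for sex, 0 for genotype by diet, 1 for diet by sex, 2 for diet in males and 0 in females. Fry passed 0 lists for diet, 0 for genotype by diet, 7 for diet by sex, 2 for diet in males and 0 in females. With 2 surrogate variables 7 passed for diet by sex, 6 for diet in males and 6 in females. Cohort 1 alone passed 11 for diet and 5 for sex, and cohort 2 alone 13 for diet, 14 for sex, 4 for diet in males and 16 in females.

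Trem2 for genotype lay between −0.041 and 0.010 with 1 library left out, and its sign turned to 0.048 in cohort 2 alone, 0.010 without female_wildtype_western replicate 12 and 0.0026 without male_wildtype_chow replicate 29, and that of C4b to 0.013 without the 3 choroid plexus libraries. For sex, the near-empty row Ddx3y turned to 0.066 in limma-voom and 0.13 in cohort 2 alone, Usp9x to 0.0072 in cohort 2 alone and Mobp to −0.0012 with 2 surrogate variables. Fkbp5 for diet by sex turned to −0.020 with 2 surrogate variables and −0.0018 in cohort 2 alone. None of these was called in any of these settings. The depth limits what can be said of genes with a wildtype mean under 2 CPM, such as Cst7, Galnt5, Gdf3, RT1-Ba and RT1-Da. For genotype by diet the simulated tables gave 20 of 50 calls for a 1.2-fold and 39 of 50 for a 1.5-fold difference, so its count of 0 excludes few small effects.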

Other observations

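The contrasts were planned, while the gene lists for diet by sex, diet in males and diet in females were tested after the results were seen.

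Several further lists differed in their diet effect between the sexes at the preset correlation and were lost with an estimated one. Homeostatic microglia genes had a lower diet effect in females, with 3 of 14 members called, 5 adjusted over the list alone and a median of −0.13 (adjusted p = 0.00153, and adjusted p = 0.265 with an estimated correlation), the list mean being higher on the western diet in 7 of 8 male and lower in 5 of 6 female libraries. Clock genes had 2 of 14 called and higher in females (3 adjusted over the list alone, median 0.072, lower in 7 of 8 male and higher in 6 of 6 female libraries on the western diet, adjusted p = 0.00153, and adjusted p = 0.189 with an estimated correlation). Per1, a clock gene that also responds to glucocorticoids, differed by 0.71 ± 0.11, while Dbp (−0.14 ± 0.095) and Nr1d1 (−0.15 ± 0.079) did not pass. Reactive astrocytes (median −0.17, adjusted p = 0.00960, and adjusted p = 0.267 with an estimated correlation) and complement (−0.14, adjusted p = 0.00506, and adjusted p = 0.406 with an estimated correlation) were lower in females with 0 members called, each lower on the western diet in 5 of 6 female libraries and higher in 6 and 5 of 8 male ones. In males alone the western diet went with higher oxidative phosphorylation genes (64 of 72 values above 0, higher in 7 of 8 libraries, median 0.042, adjusted p = 3.97e-08, and adjusted p = 0.392 with an estimated correlation) and higher homeostatic microglia genes (11 of 14 above 0, 7 of 8 libraries, median 0.093, adjusted p = 0.000164, and adjusted p = 0.246 with an estimated correlation). In females alone it went with lower fatty acid synthesis genes (4 of 16 above 0, lower in 5 of 6 libraries, median −0.061, adjusted p = 0.00856, and adjusted p = 0.294 with an estimated correlation), where Thrsp stood at −0.29 ± 0.063, lower in 6 of 6.

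Markers of tissue next to the dorsal hippocampus showed no passing difference between the genotypes: the medians were 0.0055 for thalamus, 0.027 for neocortex and −0.042 for striatum (adjusted p = 0.817, 0.631 and 0.926), in the direction of the list's mean in 10, 9 and 7 of 15 libraries. For thalamus the mean was −0.020 and for striatum 0.0025, of opposite sign to the median, and the test pointed down for both. Choroid plexus markers were highest in male_alzheimer_chow replicate 30, female_wildtype_chow replicate 20 and female_alzheimer_western replicate 11, with mean centred log2 values of 1.14, 0.916 and 0.709. Neurogenesis genes had a genotype median of 0.12 with 1 of 10 called and 2 adjusted over the list alone (adjusted p = 0.104, 9 of 15 libraries). Neuronal subtype lists other than CA1 did not pass for genotype, with medians of −0.052, 0.00013 and 0.037 and an adjusted p of 0.379, 0.926 and 0.149 for dentate granule neurons, CA2 and CA3 neurons and GABAergic interneurons, in 10, 8 and 11 of 15 libraries.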
